A study of Glycine max with 7 samples.

How the data were processed

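Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where 2 transcription factors, GLYMA.04G093300 and GLYMA.06G314400, sit on the genome of soybean (Glycine max, cultivar Williams 82). Per the labels, embryos at the cotyledon stage were dissected from seeds 3.5 to 4.5 mm long and crosslinked in 1% formaldehyde. Chromatin was sheared by sonication and incubated with 2 µg of an antibody against a GLYMA.04G093300 peptide or 3 µg of an antibody against a GLYMA.06G314400 peptide. Libraries were amplified with 15 PCR cycles, per the labels. The series held 7 samples, of which 4 were ChIP libraries and 3 were input chromatin, that is sheared chromatin set aside before the antibody step. The 3 input libraries were not analysed here.

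The authors called peaks separately in each ChIP library and deposited 1 peak list per library, so replicates could be compared peak by peak. The submitters' processing notes name Bowtie 0.12.7, a read aligner, and MACS3, a peak caller, without stating their settings. The genome build, and whether the input libraries served as the control of the peak caller, are not given in the sources used here. Each deposited list gives, per peak, its start and end, the position of its summit, a fold enrichment, a −log10 p-value, a −log10 q-value and an integer score. Every peak in the deposited lists had a q-value of 0.01 or lower, read from its −log10 value. A peak's fold is a ratio computed by the authors' caller within 1 library, and it was used here only to describe, rank or filter peaks within its own list. The score column deposited by the authors was not used for any result. The lists hold no read counts, so the sequencing depth of each library is unknown, and no interval that needs it is given.

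Groups and replicate numbers came from the sample labels. Names inside the peak lists called GLYMA.04G093300 HB22 and GLYMA.06G314400 AREB3, and numbered the replicates differently. Replicates 1 and 2 of GLYMA.04G093300 were named BR3 and BR4, and replicates 2 and 3 of GLYMA.06G314400 were named BR4 and BR1. Under either numbering the 2 factors share 1 replicate number, carried by the same 2 libraries. The labels describe the replicates as biological, and no 2 lists were identical.

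Peaks were counted as shared when they overlapped by at least 1 bp. A reproducible site was a peak of 1 replicate joined with every peak of the other replicate of that factor that it overlapped. Its summit was that of the member with the highest percentile of fold within its list. Sites were ranked by the smaller of the 2 replicates' percentiles. A site was called shared when it overlapped a reproducible site of the other factor, and specific to its factor when it overlapped no peak of either library of the other factor. Sites in neither class overlapped a peak seen in only 1 library of the other factor.

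Chance overlap was measured in 2 ways with 20 draws each. In the first, each peak was placed at random on its own chromosome. In the second, added after the data were seen, each peak was moved by 5 to 50 kb, which keeps the regional density of peaks. The length of a chromosome was taken as the highest peak end in any of the 4 lists. Positions along chromosomes used the 20 chromosomes only. Intervals of 95% came from resampling the 20 chromosomes, 1000 times for shares of sites and 200 times for comparisons of sites at equal width. Equal width here means within 20 groups of equal site number formed by the rank of width, in which widths still varied. Differences along chromosomes were tested with a two-sided sign-flip permutation test with 100000 resamples over the 20 chromosomes, and the 6 tests were adjusted together by the Benjamini-Hochberg method. The 2 comparisons of specific with shared sites among them are given as values without a p, since they are not independent of the difference between the factors. The comparison of bins of 1 Mb is not reported, since its bins were split by the number of shared sites and the split partly decides its outcome. Chromosomes are not biological replicates, so these p-values say how evenly a difference in these lists holds over the genome. With 2 libraries against 2, the smallest exact two-sided permutation p is 0.333, so no test over libraries is given.

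The overlap code was checked against an exhaustive count and tested on simulated data. In 50401 simulated peaks modelled on GLYMA.04G093300 replicate 1, with 9.79%, 40.1% and 70.5% planted as shared, the share recovered beyond chance was 9.67%, 40.1% and 70.5%. These peaks were placed at random on their chromosomes and lack the regional density of the real lists. The shares in the results are overlaps as counted, with nothing taken off for chance. The simulation therefore checks the code and not those shares. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

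Choices fixed before the data were examined included the overlap rule, a stricter q of 1e-05, the 10000 peaks with the highest fold per library, an overlap of at least 50% of both peaks, and leaving out each library in turn. For the overlap between factors, the sites specific to a factor and the position on chromosomes, these alternatives had been fixed for gene results and were carried over after the data were seen. Keeping only GLYMA.04G093300 replicate 1 and GLYMA.06G314400 replicate 3, whose replicate numbers differ, had been fixed for bound genes only. The use of that pair for every result given here was decided after the data were seen. Bound genes, promoter windows, gene lists, motifs and short sequence words had also been planned and were not analysed here. They need a genome and annotation of the build the peaks use. A soybean gene table of a named assembly was tried. Between 31.9% and 33.0% of the summits of a library lay within 1 kb of a gene edge in it, against 31.2% to 33.3% when the whole list was slid along the chromosome by 20 lags of up to 100 kb. The lists therefore showed no alignment with that table, and 0 of its rows carried the identifier of either factor. The planned rule for naming genes was carried over to sites after the data were seen. For each factor it takes the 10 sites with the highest smaller percentile, and the 10 so ranked among sites specific to that factor. Coordinates are 1-based, in the system of the deposited lists, whose build is not given in the sources used here.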

Results

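The binding sites of GLYMA.04G093300 and GLYMA.06G314400 were mapped in cotyledon-stage soybean embryos with 2 ChIP libraries per factor. In the cotyledon stage the embryo of a legume has formed its cotyledons, the organs that store protein and oil in the mature seed. The peak lists name GLYMA.06G314400 AREB3, which in Arabidopsis is the name of a bZIP transcription factor of the group that binds abscisic acid response elements. GLYMA.04G093300 is named HB22 in its lists. The fold of a peak is the authors' own value for that library.

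GLYMA.04G093300 had 50665 peaks in replicate 1 and 39721 in replicate 2, and GLYMA.06G314400 had 45324 in replicate 2 and 50147 in replicate 3. The mean number of peaks was 45193 ± 7739 (SD, n = 2) for GLYMA.04G093300 and 47736 ± 3410 (SD, n = 2) for GLYMA.06G314400, a difference smaller than the spread between replicates. GLYMA.06G314400 peaks were wider, with a median of 408 ± 13.4 bp (SD of the 2 library medians, n = 2) against 316.5 ± 0.707 bp for GLYMA.04G093300. They covered 20.1 and 23.6 Mb of the genome, against 18.9 and 15.0 Mb for GLYMA.04G093300. Within the lists, the median fold was 4.22 and 3.85 in the GLYMA.04G093300 libraries and 6.44 and 6.69 in the GLYMA.06G314400 libraries. The highest fold was 32.4 and 24.0 in the former and 69.5 and 75.2 in the latter. A q of 1e-05 or lower was reached by 86.1% and 83.4% of GLYMA.04G093300 peaks and by 97.0% and 95.8% of GLYMA.06G314400 peaks. The depth of the libraries is unknown, and both the length of a list and its folds depend on it.

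The first comparison asked which peaks of a factor recurred in its other replicate. On average over the 2 directions of the comparison, 84.0% of GLYMA.06G314400 peaks and 71.4% of GLYMA.04G093300 peaks recurred. Each factor has 1 pair of replicates, so the difference between the factors has no replicate error and was not tested. Of the GLYMA.06G314400 peaks, 88.7% of those in replicate 2 overlapped a peak of replicate 3, and 79.4% of those in replicate 3 overlapped a peak of replicate 2. Of the GLYMA.04G093300 peaks, 62.7% of those in replicate 1 were found in replicate 2 and 79.99% of those in replicate 2 were found in replicate 1. The Jaccard index, the length covered in both lists over the length covered in either, was 0.659 for GLYMA.06G314400 and 0.469 for GLYMA.04G093300. Random placement gave an overlap of 4.67% for GLYMA.06G314400 and 3.68% for GLYMA.04G093300, and peaks moved by 5 to 50 kb gave 8.56% and 7.38%.

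The peaks with the highest fold recurred almost without exception. Of the 1000 highest in a list, 99.9% of those in GLYMA.04G093300 replicate 1 and 100% of those in each of the other 3 libraries had a partner in the other replicate. Among the 10% of peaks with the lowest fold, the share fell to 35.2% in GLYMA.04G093300 replicate 1 and 36.7% in GLYMA.06G314400 replicate 3, the longer list of each factor. It was 67.7% and 67.03% in the shorter lists. Summits of overlapping peaks lay a median of 22 bp apart between the GLYMA.06G314400 replicates and 46 bp apart between the GLYMA.04G093300 replicates.

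**Figure D1:**
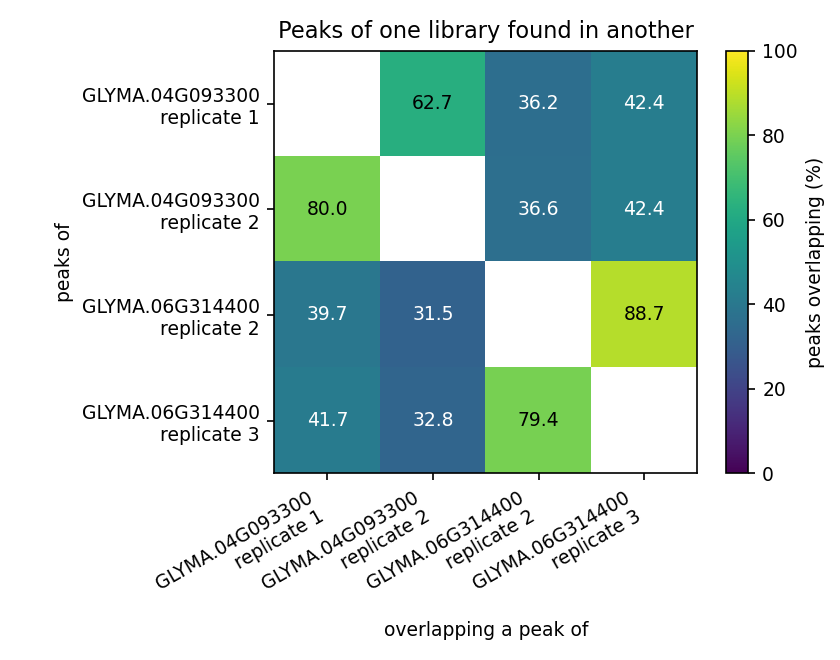
Share of the peaks of each library (rows) that overlapped a peak of another library (columns) by at least 1 bp, in percent. Shares within a factor run from 62.7% to 88.7%, and shares between factors from 31.5% to 42.4%.

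Joining the replicates gave 30906 reproducible GLYMA.04G093300 sites with a median width of 445 bp and 39590 reproducible GLYMA.06G314400 sites with a median width of 488 bp. The GLYMA.04G093300 site with the highest rank lay on chromosome 14 from 42458042 to 42458710, with a fold of 28.4 in replicate 1 and 20.3 in replicate 2. It overlapped a GLYMA.06G314400 site. The next was on chromosome 8 from 6830632 to 6831191, with folds of 28.2 and 20.2. The site with the highest single fold, 32.4 in replicate 1 and 19.2 in replicate 2, lay on chromosome 4 from 9727246 to 9728201 and was shared. The GLYMA.06G314400 site with the highest rank lay on chromosome 4 from 11188636 to 11189801, with folds of 68.5 in replicate 2 and 67.8 in replicate 3, and was shared. It was followed by 2 sites specific to GLYMA.06G314400, on chromosome 13 from 13161703 to 13162533 (folds 63.2 and 66.3) and on chromosome 19 from 27647819 to 27648693 (folds 60.9 and 66.1). The 10 highest sites lay on 7 chromosomes for GLYMA.04G093300 and on 8 for GLYMA.06G314400. With GLYMA.04G093300 replicate 2 left out, all 50665 peaks of replicate 1 stand in place of the 30906 sites.

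The second comparison asked whether the 2 factors occupied the same places. A substantial part of the sites of each factor overlapped a site of the other. Of the GLYMA.04G093300 sites, 12503 or 40.5% (95% interval over chromosomes 39.8 to 41.2) overlapped a GLYMA.06G314400 site. Of the GLYMA.06G314400 sites, 12421 or 31.4% (30.5 to 32.3) overlapped a GLYMA.04G093300 site. These shares were 8.92-fold and 8.97-fold those of random placement, and 4.63-fold and 4.64-fold those of sites moved by 5 to 50 kb. A further 15314 GLYMA.04G093300 sites (49.6%) and 20979 GLYMA.06G314400 sites (53.0%) overlapped no peak of either library of the other factor.

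Overlap within a factor exceeded overlap between factors in every pair of libraries. Of the peaks in GLYMA.04G093300 replicates 1 and 2, 36.2% and 36.6% overlapped GLYMA.06G314400 replicate 2, and 42.4% of each overlapped GLYMA.06G314400 replicate 3. Of the peaks in GLYMA.06G314400 replicates 2 and 3, 39.7% and 41.7% overlapped GLYMA.04G093300 replicate 1, and 31.5% and 32.8% overlapped GLYMA.04G093300 replicate 2. The partner library moved these shares more than the replicate itself did. The Jaccard index was 0.136, 0.149, 0.165 and 0.188 in the 4 pairs between factors, below the 0.469 and 0.659 within factors. The index follows the length of the lists, and 0.136 belonged to the pair that shares replicate number 2, which are the shorter lists of their factors. Relative to moved peaks, the overlap of that pair was 4.85-fold (SE 0.0175 over draws) and 4.84-fold (SE 0.0201) in the 2 directions, and that of the other pairs was 4.76-fold to 4.83-fold. The share of overlapping sites depended on what counted as overlap and on how many peaks entered. It was 26.9% and 18.8% for GLYMA.04G093300 and GLYMA.06G314400 when the overlap had to reach 50% of both peaks. With the 10000 highest peaks of each library and the overlap rule unchanged, it was 16.5% and 12.9%. Fewer sites of the other factor then remain to be overlapped, and moved sites gave 2.53% and 2.04%, against 8.73% and 6.76% with all peaks. In each case the share was at least 6.32-fold that of moved sites.

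Sites with a higher fold were shared more often in the lists as called, and for GLYMA.06G314400 the direction at equal width depended on how overlap was measured. Of the 1000 highest GLYMA.04G093300 sites 61.3% were shared, and of the 1000 highest GLYMA.06G314400 sites 43.9%. In the 10% of GLYMA.04G093300 sites with the lowest rank the share was 33.7%, and in the highest 10% it was 57.1%. For GLYMA.06G314400 the corresponding shares were 27.8% and 41.9%. Within 20 groups of similar width, the upper minus the lower 50% of sites by rank differed by 5.86 points (95% interval 5.10 to 6.49) for GLYMA.04G093300. For GLYMA.06G314400 the difference was -4.38 points (-4.92 to -3.75). With summits within 100 bp in place of overlapping edges, the differences at equal width were 4.38 points (3.73 to 5.08) and 1.51 points (0.961 to 2.05). Shared sites were wider than specific ones, with medians of 496 against 409 bp for GLYMA.04G093300 and 555 against 449 bp for GLYMA.06G314400. The median fold of shared against specific GLYMA.04G093300 sites was 5.29 against 4.60 in replicate 1 and 4.32 against 3.92 in replicate 2. For GLYMA.06G314400 it was 8.09 against 6.74 in replicate 2 and 9.81 against 7.47 in replicate 3.

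**Figure D2:**
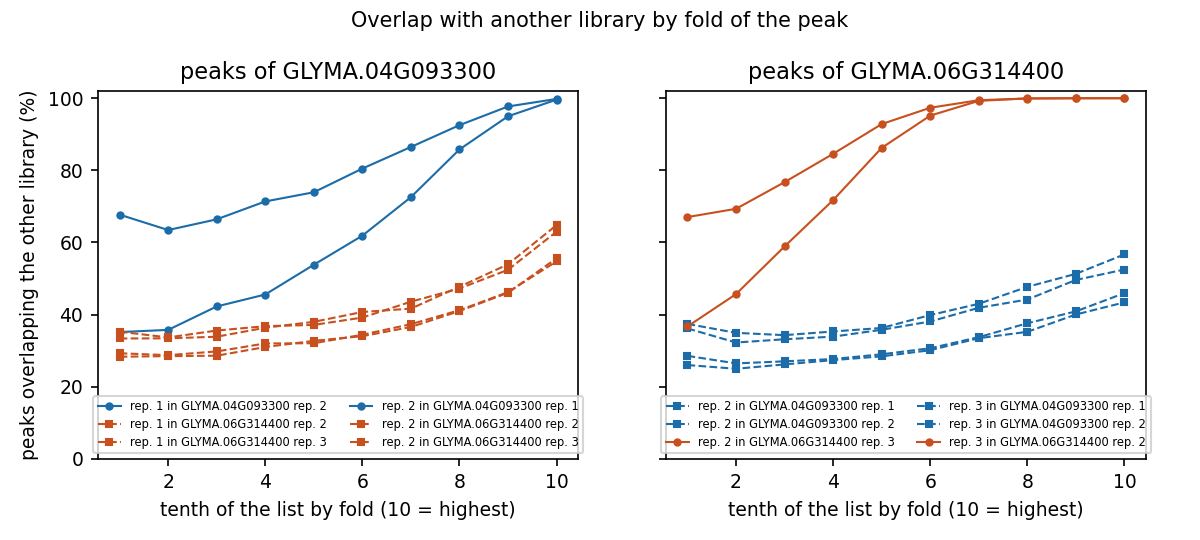
Share of peaks overlapping another library, in percent, for peaks grouped into 10 equal parts of their own list by fold, from lowest (1) to highest (10). Solid lines are pairs of replicates and dashed lines are pairs between factors; the overlap between factors of the 1000 highest peaks runs from 44.2% to 75.7%.

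Strong sites were also found that belonged to 1 factor alone. Of the 10 highest GLYMA.04G093300 sites, 7 were shared and 2 were specific, and of the 10 highest GLYMA.06G314400 sites, 4 were shared and 6 were specific. Among the 1000 highest sites, 256 GLYMA.04G093300 sites and 409 GLYMA.06G314400 sites were specific. The highest sites specific to GLYMA.04G093300 lay on chromosome 2 from 45775407 to 45776059 (folds 24.6 and 17.8 in replicates 1 and 2), on chromosome 13 from 32211967 to 32212953 (22.5 and 17.1) and on chromosome 1 from 16519645 to 16520319 (21.9 and 19.2). The third highest site specific to GLYMA.06G314400 lay on chromosome 18 from 19420816 to 19421666 (folds 55.0 and 66.5 in replicates 2 and 3), and the fourth on chromosome 5 from 7031474 to 7032397 (64.4 and 56.5). Absence from the other factor's lists means that no peak reached the authors' threshold there. With GLYMA.04G093300 replicate 2 left out, 28113 peaks of replicate 1 were specific in place of 15314 sites.

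Few regions ranked among the highest sites of both factors. Of the 1000 highest GLYMA.04G093300 sites, 47 overlapped 1 of the 1000 highest GLYMA.06G314400 sites, more than the 15.5 expected if the rank of the partner did not matter. That expectation leaves out width. The median width of GLYMA.06G314400 sites was 744 bp in the highest 10% by rank and 373 bp in the lowest 10%. The region that ranked highest in both lay on chromosome 6 from 8390567 to 8391614. Its fold was 24.6 and 18.4 in the GLYMA.04G093300 replicates and 48.9 and 47.3 in the GLYMA.06G314400 replicates, and the 2 summits were 121 bp apart. The next lay on chromosome 4 from 46558414 to 46561068, with folds of 19.7 and 11.5 for GLYMA.04G093300 and 53.3 and 53.1 for GLYMA.06G314400 and summits 264 bp apart. In a region on chromosome 13 from 20155052 to 20155853 the summits were 58 bp apart, with folds of 23.6 and 13.8 for GLYMA.04G093300 and 41.1 and 45.2 for GLYMA.06G314400. These 3 regions were chosen after their values were seen.

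Where the factors overlapped, their summits lay farther apart at the median than those of replicates. Of the overlapping sites, 39.0% had summits within 100 bp of each other, against 76.8% of overlapping peaks between GLYMA.04G093300 replicates and 93.3% between GLYMA.06G314400 replicates. The median distance between the summits of overlapping sites was 136 bp, against 269 bp for moved sites that overlapped by chance. In the 4 pairs of libraries between factors the median was 110, 112, 134 and 137 bp, above the 46 and 22 bp between replicates. Counted over all sites, 2480 pairs of GLYMA.04G093300 and GLYMA.06G314400 summits lay less than 50 bp apart, 9.56-fold the number for moved sites. The ratio was 5.46 at 150 to 200 bp and 1.78 at 350 to 400 bp, and it was still 1.60 at 1950 to 2000 bp.

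**Figure D3:**
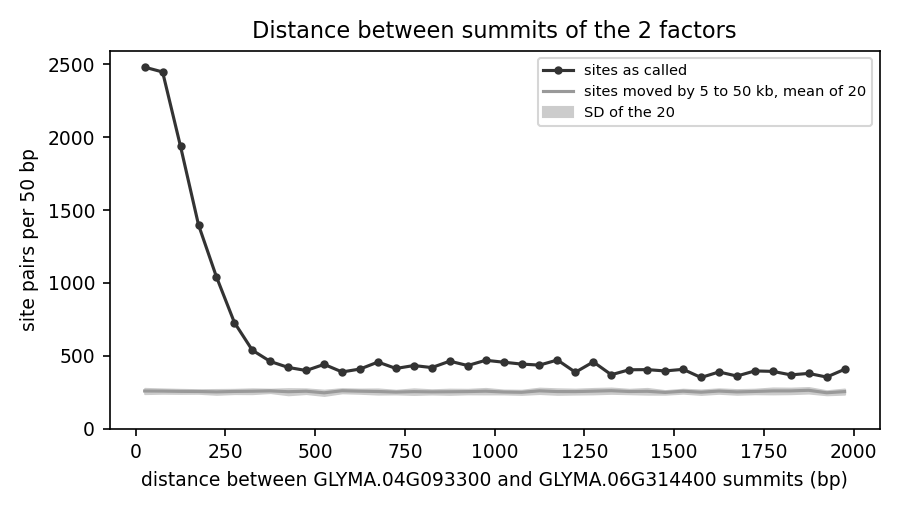
Number of pairs of GLYMA.04G093300 and GLYMA.06G314400 site summits per 50 bp of distance, for sites as called and for GLYMA.04G093300 sites moved by 5 to 50 kb (mean and SD of 20 draws). The observed number starts at 2480 pairs and falls to 462 at 350 to 400 bp, while moved sites give 247 to 264 pairs.

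The third comparison, made after the data were seen, concerned where on the chromosomes the peaks of the factors lay. With the 20 chromosomes pooled, the peaks of both lay mainly towards the chromosome ends. In soybean the ends hold most of the genes, while the regions around the centromeres are rich in repeats. Chromosome 13 was an exception, with 53.2% of its GLYMA.04G093300 sites and 55.1% of its GLYMA.06G314400 sites in the middle 50%. The outermost 10% of the chromosome span at each end together held 41.3% ± 0.0421 of GLYMA.04G093300 peaks and 39.4% ± 0.369 of GLYMA.06G314400 peaks (SD, n = 2 each). GLYMA.06G314400 peaks lay slightly more often in the middle 50% of the span, at 21.7% ± 0.352 against 19.9% ± 0.00281 for GLYMA.04G093300 (SD, n = 2 each). Both GLYMA.06G314400 libraries lay above both GLYMA.04G093300 libraries, which chance gives in 33.3% of such designs, counting either direction.

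**Figure D4:**
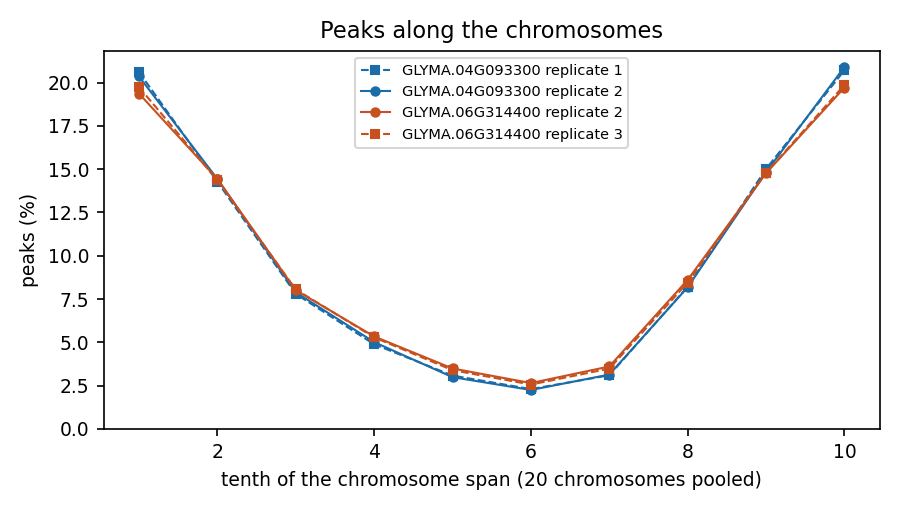
Share of the peaks of each library, in percent, in 10 equal parts of the chromosome span, with the 20 chromosomes pooled. All 4 libraries are lowest in part 6, at 2.24% to 2.64%, and GLYMA.06G314400 is lower than GLYMA.04G093300 in the outermost parts.

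Across the 20 chromosomes, the share of reproducible sites in the middle 50% averaged 20.4% for GLYMA.06G314400 and 18.2% for GLYMA.04G093300. The difference of 2.25 percentage points (SE 0.291 over chromosomes) was in the same direction on 19 of 20 chromosomes (sign-flip permutation p = 1e-05, the smallest 100000 resamples can give, adjusted p = 1.5e-05). In the middle 20% it was 0.906 points (SE 0.225, higher on 17 of 20 chromosomes, permutation p = 0.00071, adjusted p = 0.000852). Shared sites are the same places for both factors, so this difference lay in the remaining sites by construction. Among sites specific to a factor it was 3.78 points (SE 0.408), with GLYMA.06G314400 higher on 20 of 20 chromosomes (permutation p = 1e-05, adjusted p = 1.5e-05), which is not a separate result. The share in the middle 50% was 22.1% for sites specific to GLYMA.06G314400 and 18.3% for those specific to GLYMA.04G093300, against 17.9% for the shared sites of each. Specific minus shared sites differed by 4.25 points (SE 0.587, higher on 20 of 20 chromosomes) for GLYMA.06G314400. For GLYMA.04G093300 the difference was 0.417 points (SE 0.442, higher on 11 of 20). These values are not independent of the difference between the factors. They show which factor's specific sites departed from the shared ones. With sites pooled over chromosomes, the difference between the factors was 1.99 points, and it was 3.04 points with the 10000 highest peaks of each library.

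**Figure D5:**
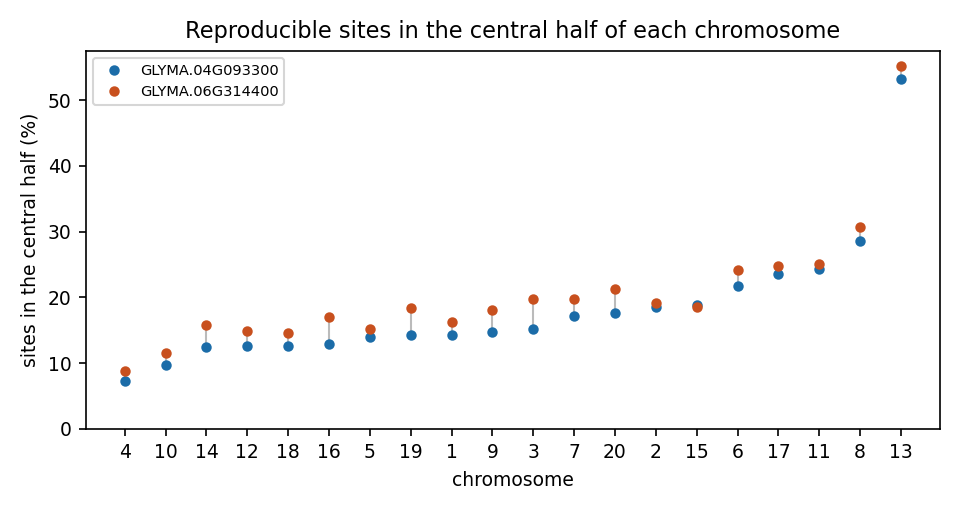
Share of reproducible sites in the middle 50% of each chromosome, in percent, for both factors, with chromosomes ordered by the GLYMA.04G093300 value. GLYMA.06G314400 is higher on 19 of 20 chromosomes. Chromosome 13 holds the highest share for each factor, 53.2% for GLYMA.04G093300 and 55.1% for GLYMA.06G314400.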

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

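Summits within 100 bp, the middle 20% of the chromosomes, and every alternative for the overlap between factors, for specific sites and for position on chromosomes were chosen or carried over from gene results after the data were seen. Both factors overlapped more than moved sites did under every alternative run, between 4.65-fold and 10.2-fold, and the excess of GLYMA.06G314400 in the middle of the chromosomes kept its direction in each. At a q of 1e-05 the share of overlapping sites was 40.9% for GLYMA.04G093300 and 27.7% for GLYMA.06G314400. With the 10000 highest peaks per library it was 16.5% and 12.9%, there were 6370 and 8121 reproducible sites, 4991 and 6298 of them specific, and the difference in the middle 50% was 3.04 points. These counts are lower by construction, since fewer peaks enter. The overlap by chance also falls with fewer peaks, and moved sites then gave 2.53% and 2.04%. With an overlap of at least 50% of both peaks the shares were 26.9% and 18.8%, and with summits within 100 bp they were 16.1% and 10.7%, while the share of GLYMA.04G093300 peaks found in the other replicate was 56.3%. With only GLYMA.04G093300 replicate 1 and GLYMA.06G314400 replicate 3, whose numbers differ, 50665 GLYMA.04G093300 peaks stood in place of sites, 29192 of them specific. The shares were 42.4% and 41.7%, and the middle 50% differed by 1.63 points. These are the longer lists of their factors. The other pairs with different numbers gave 36.2% and 39.7% with GLYMA.04G093300 replicate 1, and 42.4% and 32.8% with its replicate 2. The middle 20% differed by 0.792 points. The cause of the moves in these shares and differences was not tested. Leaving out 1 GLYMA.04G093300 library put the 39721 or 50665 peaks of the other in place of the 30906 sites. Leaving out each library of either factor in turn gave 16009 to 28113 specific GLYMA.04G093300 sites or peaks. The GLYMA.04G093300 shares were then 35.4% to 48.2% and the GLYMA.06G314400 shares 28.8% to 43.3%, with a difference in the middle 50% of 1.75 to 2.37 points. Of all values recomputed, 37 stayed within the spread between replicates or within 1.5 times the count, and 31 moved further. For the share of overlapping sites that spread, an SD of 0.122 for GLYMA.04G093300 and 1.12 for GLYMA.06G314400, averages over the same 2 partner libraries and is small, so a step from 40.5% to 40.9% counts among the 31. For the share of peaks found in the other replicate it is the SD of the 2 directions of 1 pair and reflects list length.

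No paired analysis was possible because the 2 ChIP groups share only replicate number 2 and the input libraries were not analysed here. Alternatives on promoter windows of other lengths, motif windows and backgrounds, and gene list backgrounds were not run, since no gene or sequence result was computed. If the same input libraries served as control for both factors, part of the overlap may come from them. This could not be simulated from peak lists. The overlap of 42.4% and 41.7% between GLYMA.04G093300 replicate 1 and GLYMA.06G314400 replicate 3, whose numbers differ, does not exclude it. Unknown depth limits any statement on the number of sites and on sites called specific to a factor.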

Other observations

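The tests on pairs with different replicate numbers, on a common pile-up of reads, on peak width and on the length of the lists were chosen after the results were seen. Sites of a factor also lay near other sites of that factor. Of the GLYMA.04G093300 sites, 35.0% (95% interval 34.1 to 35.9) had another GLYMA.04G093300 summit within 2 kb, against 12.7% with random placement and 24.4% with sites moved by 5 to 50 kb. For GLYMA.06G314400 the shares were 31.0% (30.3 to 31.7), 15.8% and 26.7%. The densest window of 20 kb for GLYMA.04G093300 lay on chromosome 10, where 12 summits stood between 41240280 and 41260253 with 3 GLYMA.06G314400 summits among them. For GLYMA.06G314400 it lay on chromosome 4, with 11 summits between 1656183 and 1675068 and 4 GLYMA.04G093300 summits among them. These windows were chosen after their values were seen.

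The sites of the 2 factors overlapped more often than chance. A preference for the same broad regions is argued against as the whole cause by moved sites, which overlapped only 0.216 times as often. Moved sites still overlapped more often than randomly placed ones, with 8.73% against 4.53% for GLYMA.04G093300 and 6.76% against 3.50% for GLYMA.06G314400. Moves of at least 5 kb cannot test smaller regions. A chromatin batch shared by replicate number is also argued against as the whole cause. Pairs with different numbers overlapped at least 4.76 times as often as moved peaks. Whether such a batch added to the overlap cannot be told apart, because the Jaccard index of the replicate-2 pair, 0.136, follows its short lists, although a value no higher than in the other pairs had been set as the bound. Relative to moved peaks, that pair was the highest, at 4.85-fold and 4.84-fold in the 2 directions, against 4.76-fold to 4.83-fold in the others. Only 1 pair shares a replicate number, so this small excess decides nothing. If a common pile-up of reads in both ChIPs caused all of the overlap, summits would lie as close between factors as between replicates. The smallest median distance between factors was 110 bp, against 46 and 22 bp, which argues against it as the whole cause. This median says nothing about the 37.5% to 46.5% of overlaps between libraries with summits within 100 bp. Overlaps by chance, with a median of 269 bp for moved sites, also lengthen it. Regions of high signal whatever the antibody, such as open chromatin, stay open as a candidate explanation. The 1000 highest sites overlapped the other factor more often than all sites did, by at least 12.5 points. That smallest excess is the one of GLYMA.06G314400, and wider peaks may produce it. At equal width, the overlap of its higher-ranked minus its lower-ranked sites was -4.38 points (-4.92 to -3.75). With summits within 100 bp it was 1.51 points (0.961 to 2.05). For GLYMA.04G093300 these differences were 5.86 and 4.38 points. The 12.5 points therefore decide nothing about such regions. Binding of both factors to the same regulatory regions also stays open and was not tested.

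The overlap between factors rose with fold, and wider peaks could produce that by themselves. Between the upper and the lower 50% of GLYMA.04G093300 sites by rank, the shared percentage differed by 11.4 points. Within 20 groups of similar width it differed by 5.86 points (95% interval 5.10 to 6.49). This argues against width as the whole cause, as far as the groups hold width equal, since widths still varied within a group. For GLYMA.06G314400 the difference was 8.51 points and turned to -4.38 points (-4.92 to -3.75) at equal width, so width may account for its rise. With summits within 100 bp, a measure that does not use peak edges, the difference at equal width was 4.38 points (3.73 to 5.08) for GLYMA.04G093300 and 1.51 points (0.961 to 2.05) for GLYMA.06G314400. Why the 2 measures part for GLYMA.06G314400 was not tested.

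GLYMA.06G314400 sites lay more often in the middle of the chromosomes. Weaker sites reached only in its lists are argued against by the 10000 highest peaks per library, where the difference was 3.04 points, against 1.99 points with all peaks. Irreproducible peaks can enter the difference counted over peaks, 21.7% against 19.9% in the middle 50%. A reproducible site holds only peaks that overlapped in both replicates, so they enter the difference between sites only through chance overlap. Peaks moved by 5 to 50 kb overlapped the other replicate at 8.56% for GLYMA.06G314400 and 7.38% for GLYMA.04G093300. The test of irreproducible peaks therefore decides nothing about the sites. The share of GLYMA.06G314400 peaks found in the other replicate, in the middle 50% minus outside it, was -2.13 points in replicate 2 and 0.534 points in replicate 3. A drop of over 5 points had been set as the bound before that share was computed. Reads that map to several places in the same way in both replicates, the antibodies themselves, and a difference in binding between the factors stay open and untested.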
